A study of Mus musculus with 32 samples.

How the data were processed

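The study sequenced polyadenylated RNA of mouse brain from reciprocal F1 crosses of CAST/EiJ and C57BL/6J and from the parental strains. Per the labels' protocols, each embryonic sample combined the RNA of 4 to 5 individuals and each adult sample 8 to 10 pooled animals of a single sex. RNA had an integrity score above 9, cDNA was primed with random hexamers, inserts of about 200 bp were selected and reads of 36 cycles were taken on an Illumina instrument. Technical replicates, 4 per embryonic and 2 per adult F1 pool and 2 per embryonic parental strain, were summed by the authors, and each adult parental sample has 1 library. The series holds 32 libraries: 24 of F1 brain, which make the 10 pools compared here, and 8 of the parental strains. The 4 embryonic parental libraries were used. The other 4 were left out because the values listed for them are identical for both adult regions and cannot be tied to either.

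Per the submitters' processing notes, reads were aligned with Novoalign to the mm9 genome, to transcripts and to a database of functional RNAs, and counted at bases that differ between the strains (SNPs). The values are counts: the deposited tables give, for each SNP, the number of reads with the CAST base and with the B6 base in each pool. Every listed SNP had at least 1 read in every pool of its region, so a gene silent in any pool of a region is missing from that region. The alignment of the reads itself was not repeated. The SNP positions were compared with the mouse genome assembly NCBIM37, the same build as mm9, and all lay within the chromosome lengths. Gene positions came from GENCODE vM1 on that assembly, which held 12531 of the 18464 symbols. Names of RefSeq accessions came from a GRCm38 table used for names alone.

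Repeated listings of the same position in the same transcript were dropped, 2073 in the embryonic, 1056 in the POA and 911 in the PFC table. Reads were then summed over the SNPs of the transcript with most reads for each gene. Reads placed on the mitochondrial genome were set apart and are given in the closing section. Atpase6, placed on chromosome 1, stayed among the autosomal genes, though its reads may be mitochondrial, as weighed in that section. SNPs less than a read length of 36 bases apart can count the same read more than once. The reads do not tell the strand, so genes that overlap share counts: Snrpn with Snurf, Mest with Copg2, Peg3 with Usp29, Nap1l5 with Herc3 and Mcts2 with H13. Close copies such as Srp54a and Srp54b, or the Xlr3 genes, may share reads as well. Genes that the tables list by RefSeq accession were given their symbols: Peg13, Kcnq1ot1, Nctc1, Xist (NR_001463 and NR_001570) and Tsix. These names, like the older symbols Gtl2 for Meg3, 1810044A24Rik for Trappc9, Jarid1c for Kdm5c and nS7 for Magel2, were matched after the tables were seen. Transcripts named by an accession of a cDNA (AK, AF, AJ or BC) have a chromosome but no position.

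The embryonic tests used 14652 genes, the POA 11856, the PFC 11347 and all adult pools 11136, each with a mean of at least 20 informative reads per pool. The maternal share is the CAST percent in F1i and the B6 percent in F1r. With 20 reads a share is known only roughly, and the Clopper-Pearson 95% intervals of single pools cover counting error alone. A gene was called maternal or paternal at a Benjamini-Hochberg adjusted p under 0.05 when its maternal share also lay on the same side of 50% in both crosses. In the embryo, with a single pool per cross, a two-sided Fisher's exact test compared the alleles between the crosses, and 0.5 was added to each cell for the log2 value. In the adults edgeR 4.0.16 fitted allele counts with the quasi-likelihood method. Each pool gave a CAST and a B6 count, with a term per pool, a term for the allele and a term for allele by cross. The same fit gave the strain bias. Fits over both regions held an allele by region term. Differences of parental bias between sexes, regions and ages were tested as allele by cross by factor terms on the adult pools, or on all 10 pools for age. The sex and age tests used autosomal genes.

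Expression was compared on informative reads per gene, scaled by TMM and fitted by edgeR's quasi-likelihood method, with filterByExpr as the filter. Cross and sex were covariates for region, cross and region for sex, and cross for age. The share of X-linked reads was summed over genes per pool. For the parental strains the log2 CAST to B6 ratio was compared with that of the F1 alleles, with a pseudocount of 1. Entries of the functional RNA database with identical counts were merged, and single genomic bases were tested one by one with the tests named above. Called bases were joined into clusters where gaps were at most 500 kb and at least 5 bases fell together. Mitochondrial copies in the nuclear genome were found with blastn 2.17.0 on sequence taken by samtools 1.23.1, over at least 500 bp. Median maternal shares of genes outside the imprinted lists were taken in 10 Mb windows with at least 15 genes of at least 50 reads in each pool.

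Gene lists, tests, groups and the rule for naming genes were fixed before the data were examined. The lists were imprinted genes expressed from the maternal allele, from the paternal allele and with isoform or tissue dependent imprinting, genes that escape X inactivation with Xist, Y-linked genes, progenitors, immature neurons, oligodendrocytes, astrocytes, microglia, endothelial and mural cells, choroid plexus, blood, cortical excitatory neurons, GABAergic neurons, preoptic and hypothalamic neurons, synaptic transmission, immediate early genes, and monoamine and serotonin genes. For parental bias the rule names up to 15 called members of the imprinted lists by reads per region, every member called against its list, and outside the lists the 5 autosomal calls of smallest adjusted p per direction. For strain bias and for differences it names the 5 calls of smallest adjusted p per direction and called members of the imprinted lists. For expression it names the 5 largest log2 fold changes per direction with a mean of at least 50 reads and up to 4 called members per list. Genes named beyond the rule were chosen after their values were seen. Some genes under the rule are not reported here.

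The pipeline was tested on simulated data with 200 changed genes per setting. At maternal or paternal shares of 60, 75 and 95%, the embryonic test recovered 69.0, 95.0 and 100% of genes, the POA test 0, 92.5 and 100%, the PFC test 3, 92.5 and 100%, and the test of all adult pools 46.5, 100 and 100%. Strain biases of 60 and 75% were recovered for 40.5 and 100%. A share of 75 or 95% against 50% was recovered for 96.5 and 100% between sexes, 50 and 100% between regions and 94 and 100% between ages. Expression changes of 1.5, 2 and 4-fold were recovered for 38.5, 88 and 99.5% between regions and between sexes, and for 0, 0 and 75.5% between embryo and adult.

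Alternatives fixed before the data were examined were DESeq2 1.42.0 Wald tests (size factors of 1 for alleles), DESeq2 size factors in edgeR, tests with counting error alone, edgeR with the spread of the adult pools for the embryo, and a share of at least 70% in both crosses. They also covered no rule on sides, a mean of at least 50 reads or no minimum beyond 1 read, the deepest SNP of each gene, omission of SNPs with an allele under 2% of reads, autosomes alone, no covariates, medians over X-linked genes, a pseudocount of 5 and omission of each pool. SNPs at least a read length apart, and autosomes alone for the embryo and for age, were added after the data were seen. Where omission left a group with a single pool, that pool was taken to vary like the others. A block for technical replicates was not possible because they were summed. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.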

Results

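Messenger RNA of the mouse brain was sequenced allele by allele in F1 offspring of reciprocal crosses between CAST/EiJ (CAST), an inbred strain derived from wild Mus musculus castaneus, and C57BL/6J (B6), the standard laboratory strain. In the F1i cross the mother was CAST and the father B6, and in the F1r cross the mother was B6 and the father CAST. A read over a base that differs between the strains (an informative read) tells which parental chromosome it came from, and the exchange of mothers and fathers separates an effect of the parent from an effect of the strain. Whole brain at embryonic day 15 (E15) gave 1 RNA pool per cross. The preoptic area (POA), a region at the front of the hypothalamus, and the medial prefrontal cortex (PFC) of 5-week-old adults gave 4 pools each, a male and a female pool per cross. The 10 pools came from 24 libraries whose technical replicates were summed. Informative reads numbered 11434864 and 11886213 in the embryonic F1i and F1r pools, 3599769 to 7694654 in the POA pools and 4958235 to 7462745 in the PFC pools. Values below are maternal shares, the percent of a gene's informative reads that came from the mother's allele, as mean ± SD over pools (n = 2 in the embryo, 4 in each adult region and 8 in all adults). The accompanying log2 value ± SE compares the CAST to B6 ratio between the crosses. It is positive when the maternal allele was higher, and a maternal share of 75% in both crosses corresponds to about 3.17. Intervals on single pools cover counting error only.

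The embryonic pools were compared to find genes read mainly from the mother's or the father's allele in the developing brain. Meg3, a noncoding RNA of the imprinted Dlk1-Dio3 region (chromosome 12:110779211-110809936, mm9), was 97.2% ± 2.94 maternal, and H19, a noncoding RNA beside the growth factor gene Igf2 (chromosome 7:149761434-149764048), was 98.4% ± 1.62 maternal. Almost all reads of Peg3, a zinc finger gene linked to maternal behaviour (chromosome 7:6656603-6683132), came from the father, with a maternal share of 0.710% ± 0.848. The same held for its neighbour Usp29 at 1.18% ± 1.37, for the noncoding RNA Peg13 at 1.30% ± 1.67, for Snrpn, a splicing factor gene of the Prader-Willi region (chromosome 7:67127388-67285105), at 1.38% ± 1.06, and for the retrotransposon-derived Peg10 at 1.38% ± 0.998. Of the 25 tested members of the list of genes expressed from the paternal allele, 22 were called paternal and none maternal, and 22 were called when adjusted over the list alone. Of the 27 tested members of the list expressed from the maternal allele, 14 were called maternal and 1 paternal, and 15 were called when adjusted over the list alone. Of 12 tested genes whose imprinting depends on isoform or tissue, 2 were called maternal, also when adjusted over the list alone. These were Copg2, a coat protein gene that overlaps Mest, and Grb10, which encodes an inhibitor of growth factor signalling, both named after their values were seen.

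Several imprinted genes had partial biases in the embryo. H13, a signal peptide peptidase gene (chromosome 2:152495197-152534406), was 91.2% ± 2.36 maternal, and Trappc9, a vesicle trafficking gene that holds Peg13 in an intron (chromosome 15:72420051-72891634), was 78.2% ± 1.39 maternal with a log2 value of 3.69 ± 0.15. Maternal leans near an even share were called for the synaptic scaffold gene Ppp1r9a at 51.8% ± 0.782 and for the tetraspanin gene Cd81 at 52.5% ± 1.11. The maternal share was 29.0% ± 6.91 for Igf2 itself (chromosome 7:149836673-149852721), 6.51% ± 2.13 for the phosphatase gene Inpp5f (chromosome 7:135754842-135839939) and 4.02% ± 2.66 for Mest (chromosome 6:30673547-30698457). Snurf, which shares its transcript with Snrpn, had a maternal share of 0.665% ± 0.823. Begain, which encodes a postsynaptic scaffold protein (chromosome 12:110270397-110291589), stood on the maternal list but was 39.1% ± 1.63 maternal, a paternal call at log2 -1.27 ± 0.20. Outside the lists the autosomal calls of smallest adjusted p included 4 unnamed transcripts on chromosome 12, AK017440, AJ517767, AK157178 and AF498302, all between 98.2% and 98.5% maternal, and Atpase6 at 99.3% ± 0.805 on chromosome 1. The maternal share of Atpase6 lay within 0.457 percentage points of that of mitochondrial reads in every pool, so its calls here and below may not be those of a nuclear gene. On the paternal side the calls included AF217545 on chromosome 6 at 0.731% ± 0.545 and the chromosome 7 transcripts AF365932 at 0.926% ± 0.994, BC070450 at 1.71% ± 1.60 and AK080655 at 5.85% ± 5.58. Hm13 on chromosome 2, a second symbol of H13 that was tested as a separate transcript, was also among them, at 18.4% ± 4.12 maternal. Under that symbol it is counted outside the lists.

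In all, Fisher's exact test with Benjamini-Hochberg adjustment called 835 of 14652 genes in the embryo, 570 maternal and 265 paternal, from 3429 with an unadjusted p under 0.05. With a share of at least 70% for the same parent in both crosses 75 were left, 31 maternal and 44 paternal. Of the 835 calls 39 were on the imprinted lists and 796 were not, and 78 of the latter were X-linked genes called maternal. The 718 autosomal calls outside the lists were weak, with a median maternal share of 55.2% among the 476 maternal and 44.2% among the 242 paternal calls. The test compares these 2 pools with counting error alone, so it holds no measure of the spread between pools. Counting only the deepest base of each gene gave 477 calls, and fitting the same pools with the spread of the adult pools in edgeR gave 104.

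In the adult POA 4 pools were compared in the same way. Meg3 was 99.2% ± 0.690 maternal (log2 15.07 ± 0.22, edgeR quasi-likelihood adjusted p = 5.87e-05). Snrpn was 0.339% ± 0.224 maternal (log2 -16.88 ± 0.12, edgeR adjusted p = 5.28e-06). Paternal expression also marked Rasgrf1, a Ras activator of neurons (chromosome 9:89804613-89921814), at 0.466% ± 0.218 maternal, Peg3 at 0.503% ± 0.449, Peg13 at 0.752% ± 0.674, Peg10 at 0.381% ± 0.289 and Ndn, a MAGE family gene of the Prader-Willi region, at 0.755% ± 0.378. It marked Snurf at 0.177% ± 0.147, Usp29 at 0.845% ± 0.535, the histone chaperone relative Nap1l5 at 0.641% ± 0.759 and Impact, a regulator of translation, at 4.66% ± 2.43. Partial maternal biases were called for Trappc9 at 74.9% ± 6.62, for Gnas, which encodes the alpha subunit of the stimulatory G protein, at 60.4% ± 0.863, for Ppp1r9a at 59.5% ± 5.85 and for the ubiquitin ligase gene Herc3 (chromosome 6:58781459-58870392), which is on no list and holds Nap1l5 in an intron, at 77.3% ± 2.48. Begain was again paternal, against its list, at 21.8% ± 5.04 maternal (log2 -3.73 ± 0.12, edgeR adjusted p = 0.000687). Outside the lists AK017440 at 99.3% ± 0.366, AF498301 at 97.5% ± 2.52, AF498302 at 96.2% ± 4.10 and Atpase6 at 99.7% ± 0.193 were maternal. AF217545 at 0.273% ± 0.139, BC070450 at 0.102% ± 0.204, AF365932 at 1.07% ± 0.960, AK080655 at a mean of 1.27% and DOKist4 on chromosome 7 at 9.75% ± 5.44 were paternal.

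By list, 16 of 20 genes expressed from the paternal allele were called paternal in the POA, and 20 passed when adjusted over the list alone, 18 paternal and 2 maternal. The maternal 2 were Igf2 and Ddc, the enzyme that makes dopamine and serotonin from their precursors. Of 24 genes expressed from the maternal allele 8 were called maternal and 1 paternal, and 13 passed when adjusted over the list alone. Of 10 isoform or tissue dependent genes Gnas and Copg2 were called maternal and Grb10 paternal, and the same count of 3 passed when adjusted over the list alone. Igf2, Ddc, Copg2 and Grb10 are named here after their values were seen. The edgeR test called 47 of 11856 genes, 22 maternal and 25 paternal, from 561 with an unadjusted p under 0.05, and 28 of the 47 were on the imprinted lists. Without the F1i male pool 21 genes were called and without the F1i female pool 20. Either omission ended the calls of Trappc9, Gnas, Ppp1r9a, Nap1l5, Ndn, Usp29, AF365932, AF498302, BC070450, AK080655 and DOKist4, as did the F1r male pool for Ppp1r9a and the F1r female pool for DOKist4. Without an F1i pool the only pair within a cross was the F1r male and female, whose X-linked reads were 98.9 and 31.6% maternal. X-linked genes were part of these fits, and the omissions were not run on autosomes alone. A call lost in this way need not rest on the F1i pools.

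The 4 PFC pools were compared next. Meg3 was 98.5% ± 1.89 maternal (log2 14.64 ± 0.65, edgeR adjusted p = 0.00264) and H13 88.4% ± 2.60. Peg13 was 0.972% ± 0.876 maternal (log2 -14.61 ± 0.15, edgeR adjusted p = 4.19e-06) and Snrpn 0.451% ± 0.360. Paternal calls extended to Snurf at 0.387% ± 0.310, Peg3 at 1.02% ± 1.22, Nap1l5 at 1.28% ± 1.46, Ndn at 1.39% ± 1.40, Usp29 at 2.10% ± 2.66, Rasgrf1 at 2.91% ± 2.92, the splicing factor relative Zrsr1 at 3.52% ± 2.02, Impact at 6.99% ± 6.86 and Inpp5f at 22.0% ± 4.56. Copg2 was 76.9% ± 4.16 and Trappc9 71.0% ± 9.07 maternal. Outside the lists AK017440 at 98.6% ± 1.60, AK157178 at 99.1% ± 1.10, AJ517767 at 93.2% ± 4.84, Atpase6 at 99.3% ± 0.811 and 5830418K08Rik, on chromosome 9, at 94.1% ± 2.18 were maternal. AF217545 at 1.02% ± 0.916, DOKist4 at 5.04% ± 3.40, AK080655 at 2.35% ± 3.76 and AK045535, on chromosome 7, at 0.446% ± 0.893 were paternal. So was Hm13, the second symbol of H13, at 6.76% ± 6.59. Of 17 genes of the paternal list 15 were called paternal, and 16 passed when adjusted over the list alone, the other being Igf2 as maternal. Of 19 genes of the maternal list 3 were called maternal, and 4 passed when adjusted over the list alone, the other being Begain as paternal. Of 10 isoform or tissue dependent genes Copg2 was called maternal, and 3 passed when adjusted over the list alone, with Dhcr7 and Grb10. Igf2, Begain, Dhcr7 and Grb10 are named here after their values were seen.

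The edgeR test called 32 of 11347 genes in the PFC, 12 maternal and 20 paternal, from 393 with an unadjusted p under 0.05. Of 10842 genes tested in both regions, 11 maternal and 18 paternal calls were shared, and every PFC call was also called in the embryo in the same direction. Without the F1i male pool 10 genes were called, and without the F1i female pool 10. Either omission ended the calls of Trappc9, H13, Copg2, Hm13, Impact, Inpp5f, Nap1l5, Ndn, Peg3, Rasgrf1, Usp29, AK045535, AK080655, AK157178 and DOKist4. The only pair of pools within a cross was then the F1r male and female, whose X-linked reads were 98.6 and 37.7% maternal. X-linked genes were part of these fits, and the omissions were not run on autosomes alone. A call lost in this way need not rest on the F1i pools. The calls of AK045535, AK080655 and DOKist4 also ended without the F1r male pool, and those of AK045535, AK080655 and Inpp5f without the F1r female pool, at adjusted p up to 0.632.

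All 8 adult pools were also tested together, which gave the most pools per cross. The labels do not say whether POA and PFC pools came from the same animals, so these 8 pools, here and below, may not be independent. Peg13 was 0.862% ± 0.733 maternal (log2 -14.98 ± 0.20, edgeR adjusted p = 2.48e-09), Meg3 98.9% ± 1.37 maternal (log2 14.87 ± 0.39, edgeR adjusted p = 1.2e-07) and H13 88.7% ± 2.27 maternal. Copg2 was 83.8% ± 8.32 and Trappc9 72.9% ± 7.64 maternal. Eif2c2, the Argonaute gene of RNA silencing, at 66.3% ± 19.3 and the potassium channel gene Kcnk9 at 91.8% ± 9.95 completed the maternal calls of the maternal list, and both are named after their values were seen. The paternal calls Peg10 at 0.295% ± 0.453, Snrpn at 0.363% ± 0.289, Peg3 at 0.761% ± 0.897, Nap1l5 at 0.963% ± 1.13, Ndn at 1.07% ± 1.01, Usp29 at 1.31% ± 1.89, Rasgrf1 at 1.69% ± 2.32 and Impact at 5.82% ± 4.92 had little maternal RNA, whereas Inpp5f kept 23.3% ± 3.74. Grb10 was 2.99% ± 3.35 maternal, the reverse of its side in the embryo, and is named after its value was seen. Igf2, on the paternal list, was 74.0% ± 9.65 maternal over 380 reads (log2 3.02 ± 0.31, edgeR adjusted p = 0.00239). Outside the lists AF498300, AF498301, AF498302, AK017440 and Atpase6 were between 98.9% and 99.5% maternal. AF217545, AF365932, AK045535 and AK080655 were between 0.647% and 1.86% maternal, and DOKist4 was 7.85% ± 6.69 maternal.

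The combined test called 48 of 11136 genes, 21 maternal and 27 paternal, from 613 with an unadjusted p under 0.05. Leaving out single pools left 41 to 47 calls. The calls of Eif2c2, Kcnk9 and Grb10 were not followed through these omissions, and the others named above held in each. Of 17 genes of the paternal list 15 were called paternal and 1, Igf2, maternal, and 16 passed when adjusted over the list alone. Of 20 genes of the maternal list 5 were called maternal, and 8 passed when adjusted over the list alone, with Begain, Blcap and Ppp1r9a, named after their values were seen. Of 10 isoform or tissue dependent genes Copg2 was called maternal and Grb10 paternal, and 2 passed when adjusted over the list alone. DESeq2 in place of edgeR called 91 genes, 67 maternal and 24 paternal, of which 23 were shared with the edgeR calls, and it gave no adjusted p for 6692 genes. With autosomal genes alone edgeR called 78 in all adult pools, 25 maternal and 53 paternal, 133 in the POA, 36 and 97, and 49 in the PFC, 16 and 33.

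**Figure D1:**
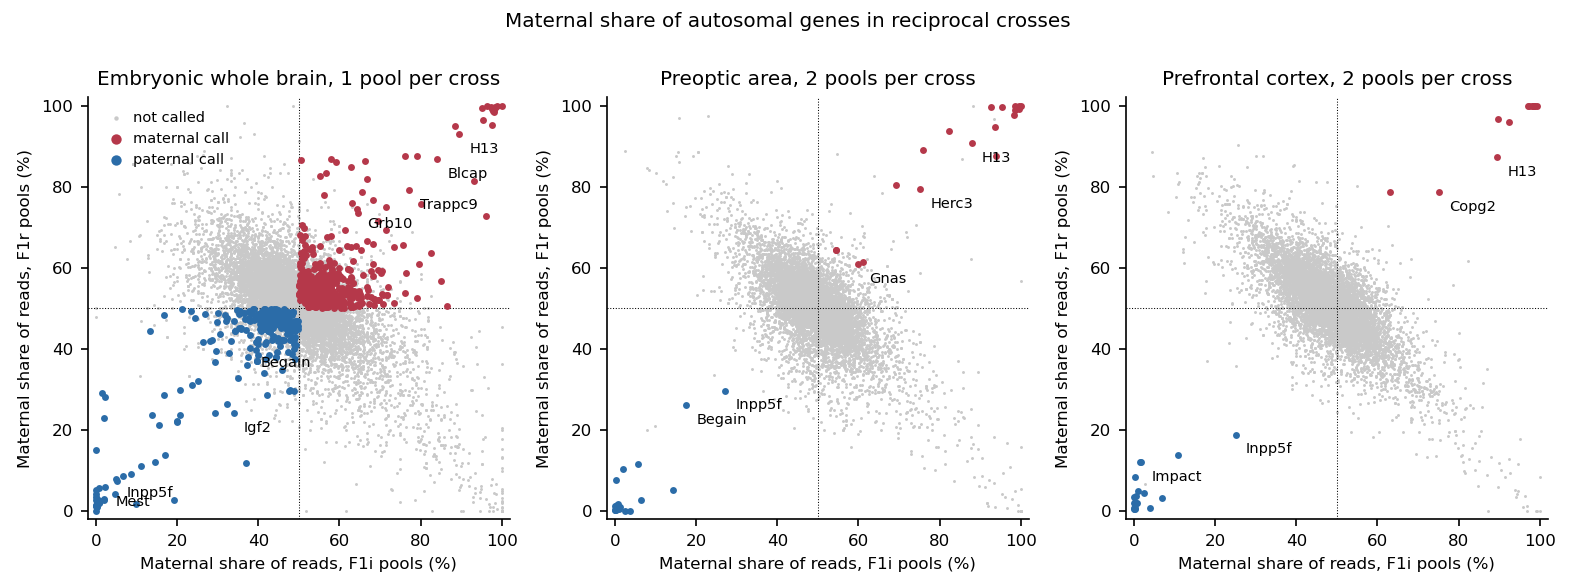
Maternal share in percent of informative reads for each tested autosomal gene in the F1i pools (horizontal axis) and the F1r pools (vertical axis), for the embryonic brain, the POA and the PFC. Genes called maternal or paternal are coloured and the others are grey. Points near the upper right corner, such as Meg3, were maternal in both crosses and points near the lower left corner, such as Peg3 and Snrpn, paternal in both.

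Male and female pools of the 8 adult pools were compared to ask whether parent-of-origin bias differs between the sexes. No autosomal gene did so in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment: 0 of 10823 genes passed, with 496 at an unadjusted p under 0.05, and DESeq2 also called 0. Within the lists 0 of 20 maternal, 0 of 17 paternal and 0 of 10 isoform or tissue dependent genes passed. Adjusted over the list alone 2 paternal genes passed and 0 on the other lists. These were Usp29, at 0.589% ± 0.622 maternal in females and 2.04% ± 2.56 in males, and Nap1l5, at 0.558% ± 0.707 in females and 1.37% ± 1.43 in males (n = 4 each), named after their values were seen. In simulated data with 200 genes changed at once, 96.5% of genes given a maternal share of 75% in a single sex, against 50% in the other, were recovered. Fewer changed genes would be harder to recover after adjustment, and sex differences in genes already biased in both sexes were not simulated. A test with counting error alone called 163 genes, and leaving out the PFC F1r female pool gave 29 calls and the POA F1i male pool 2.

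The regions were compared in the same way. Begain was 43.0% ± 2.61 maternal in the PFC and 21.8% ± 5.04 in the POA (n = 4 each), a difference of 2.92 ± 0.16 in log2 (edgeR adjusted p = 0.0192). Herc3 was 57.2% ± 4.87 maternal in the PFC and 77.3% ± 2.48 in the POA, a difference of -2.70 ± 0.19 (edgeR adjusted p = 0.038). These were the 2 genes that passed, with 471 at an unadjusted p under 0.05. Of the maternal list 1 of 20 genes passed, Begain, and 4 when adjusted over the list alone, Begain, Ppp1r9a, Blcap and Kcnk9. Ppp1r9a was 50.7% ± 0.904 maternal in the PFC and 59.2% ± 2.91 in the POA over the bases covered in both regions. Of the paternal list 0 of 17 passed, and 3 when adjusted over the list alone, Rasgrf1, Zrsr1 and Mest. Of the isoform or tissue dependent list 0 of 10 passed, and 1 when adjusted over the list alone, Copg2. Members that passed over the list alone are named after their values were seen. Leaving out any single pool ended both calls: adjusted p lay between 0.112 and 0.341 for Begain and between 0.0642 and 0.590 for Herc3, while the log2 differences stayed between 2.80 and 3.04 and between -2.90 and -2.49. DESeq2 called 17 genes, the deepest base of each gene 0, and a test with counting error alone 287.

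Between embryonic whole brain and the adult regions, 6 autosomal genes differed in parental bias, and age cannot be told apart from dissection in this comparison. Grb10 (chromosome 11:11830511-11938686) was 69.4% ± 7.24 maternal in the embryo (n = 2) and 2.99% ± 3.35 in the adult (n = 8), a log2 difference of 14.29 ± 0.75 (edgeR adjusted p = 5.97e-08). Igf2 moved the other way, from 29.0% ± 6.91 in the embryo to 81.6% ± 5.77 in the adult over the bases covered at both ages (log2 -6.86 ± 0.42, edgeR adjusted p = 3.07e-07). The paternal bias of Inpp5f was weaker in the adult, at 7.47% ± 1.89 and 23.3% ± 3.74 maternal over the bases covered at both ages (log2 -3.92 ± 0.36, edgeR adjusted p = 5.83e-05), as was that of Mest, at 4.02% ± 2.66 and 20.6% ± 10.4 (log2 -5.14 ± 0.81, edgeR adjusted p = 0.0272). The maternal bias of Blcap, a gene that surrounds the imprinted Nnat (chromosome 2:157382098-157397010), was stronger in the embryo, at 85.4% ± 1.90 and 63.2% ± 8.40 (log2 3.41 ± 0.56, edgeR adjusted p = 0.0334). Sp140, a nuclear body gene of immune cells (chromosome 1:87496953-87541612), stood at 65.2% ± 41.6 and 48.1% ± 10.9 (log2 3.58 ± 0.56, edgeR adjusted p = 0.0272). Its embryonic shares lay on opposite sides of 50%, at 93.8% in F1i and 36.2% in F1r. The deepest base alone gave Sp140 a difference of 0.90, no longer called.

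By list, 1 of 21 maternal, 3 of 18 paternal and 1 of 10 isoform or tissue dependent genes differed between embryo and adult, and 3, 5 and 1 when adjusted over the list alone. Meg3 and Igf2r on the maternal list and Peg10 and Snrpn on the paternal list passed only in this last adjustment and are named after their values were seen. The test covered 10940 genes, 457 of them at an unadjusted p under 0.05, and gave the embryonic pools the spread of the adult ones. Without the PFC F1i female pool 3 genes were called, since Blcap, Mest and Sp140 no longer passed. Blcap also failed without the PFC F1i male or PFC F1r male pool (adjusted p up to 0.0877), Mest without the POA F1i female pool (up to 0.0774) and Sp140 without the POA F1r male pool (up to 0.0877).

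**Figure D2:**
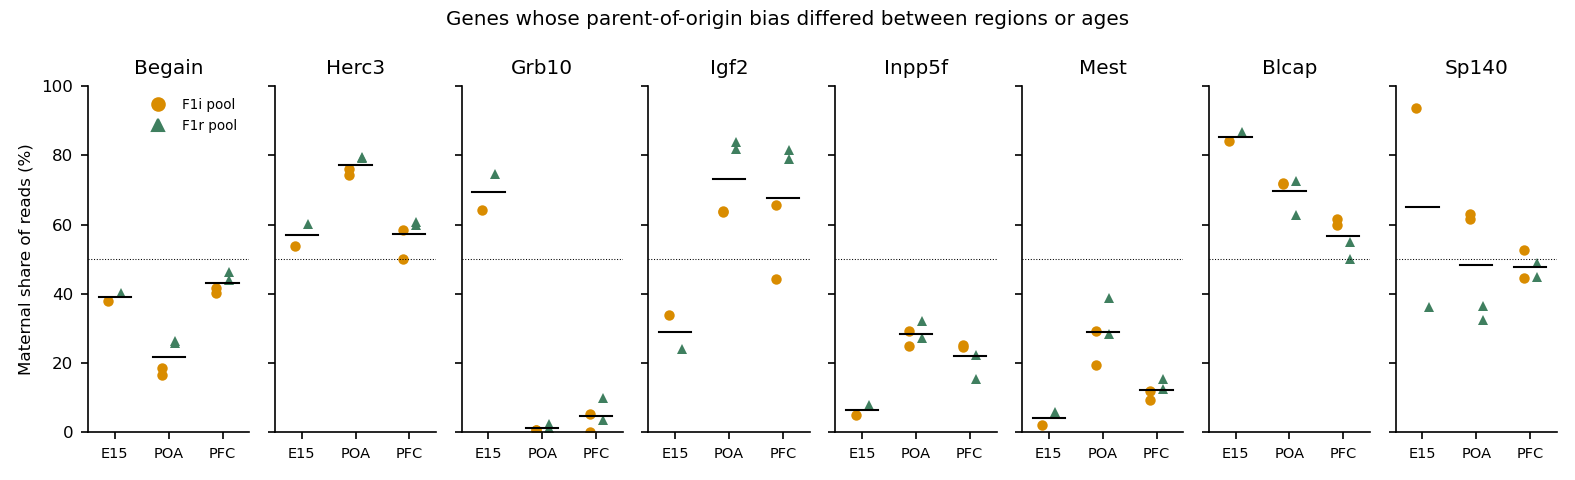
Maternal share in percent for each pool, with means, of the genes whose parent-of-origin bias differed between the adult regions (Begain and Herc3) or between embryo and adult (Grb10, Igf2, Inpp5f, Mest, Blcap and Sp140). In the age comparison Grb10 lay at 69.4% in the embryo and 2.99% in the adult, and Igf2 at 29.0% and 81.6%. The pools are drawn by tissue, each over the bases covered in that tissue, so these means need not match the points.

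Differences between the strains' own alleles were far more common than parental ones. Among genes higher from the B6 allele, the CAST share was 37.5% ± 1.78 (n = 8) for Baalc, a membrane-associated brain gene (log2 -0.74 ± 0.02, edgeR adjusted p = 2.1e-06), and 36.0% ± 9.53 for the tubulin-binding Stmn1. The ribosomal protein gene Rps15 at -0.65 ± 0.02 and the near-identical signal recognition particle genes Srp54a at -1.16 ± 0.05 and Srp54b at -1.27 ± 0.04, whose reads cannot be told apart with certainty, followed. Among genes higher from CAST, the noncoding NR_002886 had a CAST share of 97.0% ± 2.11, Retsat, a retinol saturase, 90.9% ± 2.95, Apitd1, a centromere protein gene, 88.5% ± 2.97 and Scg5, a chaperone of prohormone convertase, 66.8% ± 2.10. AK136146 had a log2 of 5.10 ± 0.15. Strain bias was also called for imprinted genes: Gnas (-0.73 ± 0.15) and the lipid transfer gene Osbpl5 (-0.32 ± 0.11) were higher from B6. Casd1 (0.39 ± 0.06), Pde4d (0.32 ± 0.07), Nap1l4 (0.25 ± 0.08), Gab1 (0.22 ± 0.06) and Cd81 (0.11 ± 0.03) were higher from CAST. Of 20 maternal, 17 paternal and 10 isoform or tissue dependent genes 3, 0 and 4 were called, and 2, 0 and 4 when adjusted over the list alone, where Osbpl5 no longer passed. With edgeR 3978 of 11136 genes were called, 2612 higher from B6 and 1366 from CAST. With a share of at least 70% for the same strain in both crosses the balance turned, to 44 higher from B6 and 70 from CAST. Without Atpase6 the CAST base held 47.2 to 49.5% of autosomal informative reads in the 8 adult pools. Whether reads with the CAST base were lost in alignment to the reference genome, and so add to the B6 calls, was not tested.

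Some of these calls ended when single pools were left out. Cd81 was lost without the POA F1r male, PFC F1i female or PFC F1r female pool (adjusted p up to 0.0559). Gnas was lost without the PFC F1i male pool, when its CAST shares stood on different sides of 50% in the 2 crosses. Gab1 was lost without any pool except the POA F1i male, PFC F1i male and PFC F1r female pools, Nap1l4 without any except the POA F1r female and PFC F1i female pools, and Osbpl5 without any except the PFC F1r male pool. Adjusted p rose to at most 0.128 for these. With the deepest base alone Nap1l4 turned to -0.39. Across 11596 genes the log2 CAST to B6 ratio of the embryonic parental strains correlated with that of the F1 alleles at Pearson's r = 0.683 and Spearman's rho = 0.555, and 68.6% of genes had the same sign. Genes are not independent replicates, and the 4 parental libraries give 1 sum per strain.

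The X chromosome showed the sex of the pools. Reads over X-linked genes in the 4 adult male pools, whose X comes from the mother, were 97.7% ± 1.28 maternal. In female pools the CAST chromosome was the more active in either cross: the maternal share was 71.1% ± 4.44 in F1i, where the mother was CAST, and 34.7% ± 4.34 in F1r, where the father was (n = 2 each). In the POA females it was 74.2% (Clopper-Pearson 95% interval 74.0 to 74.4) and 31.6% (31.4 to 31.8), and in the PFC females 68.0% (67.7 to 68.2) and 37.7% (37.4 to 38.0). The embryonic F1i pool was 97.4% maternal (97.3 to 97.4) and the F1r pool 44.5% (44.3 to 44.7). Some genes listed as escaping X inactivation were closer to an even share than X-linked reads as a whole in POA females: Ddx3x, an RNA helicase, at 59.0% (55.6 to 62.4) in F1i and 47.3% (44.1 to 50.5) in F1r, the translation factor gene Eif2s3x at 58.4% (55.1 to 61.6) and 43.0% (39.7 to 46.3), and the histone demethylase gene Kdm5c at 66.6% (60.9 to 71.9) and 40.8% (35.3 to 46.4). In the PFC F1r females, a pool with fewer Xist reads per informative read than the other female pools, Kdm5c lay at 30.8% (24.2 to 38.0). Xist, the RNA that coats the inactive X, leaned the other way in the POA females, at 33.7% (27.1 to 40.8) and 65.0% (58.6 to 71.0) maternal. Kdm6a lay at 64.7% (38.3 to 85.8) and 54.8% (36.0 to 72.7) there, over 17 and 31 reads, and 1810030O07Rik at 56.4% (39.6 to 72.2) and 32.7% (20.7 to 46.7), over 39 and 55. 2610029G23Rik was further from an even share in the POA females, at 85.6% (79.7 to 90.4) and 23.8% (18.01 to 30.5), and had 21.9% (15.3 to 29.8) maternal reads in the POA F1r male pool, unlike X-linked reads as a whole.

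**Figure D3:**
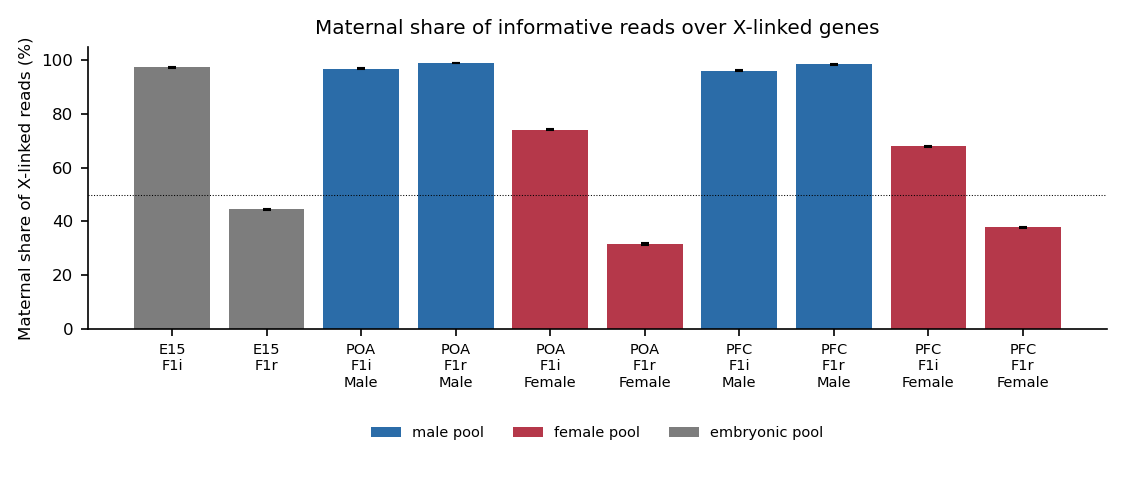
Maternal share in percent of reads over X-linked genes in each of the 10 pools, with 95% Clopper-Pearson intervals. Adult male pools lay between 96.2% and 98.9%, female pools above 50% in F1i and below 50% in F1r, and the embryonic pools at 97.4% and 44.5%.

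Total informative reads per gene were compared between the adult regions to describe their cell types and activity. The PFC was rich in RNA of cortical excitatory neurons: Slc17a7, the vesicular glutamate transporter of the cortex, reached 678 ± 67.0 CPM (informative reads scaled to a common library size) in the PFC and 1.38 ± 0.373 in the POA (n = 4 each, log2 8.87 ± 0.17), and Camk2a, a kinase of glutamatergic synapses, 6615 ± 565 and 778 ± 61.6. Nrgn, a postsynaptic calmodulin regulator, was higher in the PFC by 5.22 ± 0.16 in log2, the neuropeptide gene Cck by 5.37 ± 0.12, the secreted Nov by 6.21 ± 0.19 and the transcription factor gene Bhlhb5 by 4.85 ± 0.25. All 16 immediate early genes, which respond to neuronal activity, were higher in the PFC (median log2 2.14), with Egr1 at 436 ± 30.4 against 45.2 ± 3.60 CPM and Arc at log2 3.14 ± 0.14. Of 27 genes of synaptic transmission 18 were higher in the PFC, among them Snap25 at 1.09 ± 0.11 and Syt1 at 1.20 ± 0.12, and Cplx1 and Sv2a, named after their values were seen, in the POA. Of 13 microglial genes 9 were higher in the PFC, by 0.69 ± 0.10 for the receptor gene Csf1r and 0.64 ± 0.12 for Cx3cr1, and none in the POA.

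Preoptic, hypothalamic and oligodendrocyte genes were mostly higher in the POA. Of 15 preoptic and hypothalamic genes 12 were higher there and none in the PFC (median log2 -2.59), including the peptidase gene Ecel1 at -4.76 ± 0.21, Peg10 at -3.78 ± 0.14, Baiap3 at -3.25 ± 0.20 and Hap1, a huntingtin partner, at -2.59 ± 0.11. Agt, the precursor of angiotensin, was at 640 ± 55.9 CPM in the POA and 15.5 ± 6.18 in the PFC (log2 -5.38 ± 0.21), and AW551984 and the calcium channel subunit gene Cacna2d2 (-3.68 ± 0.19) were among the largest differences. Of 15 GABAergic genes 8 were higher in the POA, among them Gad2, which makes GABA, at -2.56 ± 0.11 and Gad1 at -1.34 ± 0.10. The 5 higher in the PFC were Cck, Npy, Sst, Vip and Pvalb, of which all but Cck are named after their values were seen. Of 12 oligodendrocyte genes 11 were higher in the POA, with myelin basic protein, Mbp, at 3628 ± 221 against 1540 ± 877. Of 13 astrocyte genes 8 were higher in the POA, such as Slc4a4 at -1.39 ± 0.10 and Ntsr2 at -1.49 ± 0.11, and Slc1a2, a glutamate transporter, was higher in the PFC at 0.61 ± 0.23. Paternally expressed imprinted genes were mostly higher in the POA, 10 of 19, with Peg3 at -1.94 ± 0.14, and 4 were higher in the PFC, Snrpn and Snurf and, named after their values were seen, Mest and Mcts2.

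Of the other lists in this comparison, 5 of 21 maternally expressed genes were higher in the PFC, such as Cobl at 1.38 ± 0.13, and 7 in the POA, such as H13 at -0.83 ± 0.11. Of 10 isoform or tissue dependent genes 4 were higher in the POA, Grb10 at -2.44 ± 0.17, Ampd3, Gab1 and Dhcr7, and none in the PFC. Among 11 progenitor genes 4 were higher in the PFC, such as the cyclin gene Ccnd2 at 1.93 ± 0.17, and 3 in the POA, such as Sox2 at -0.74 ± 0.16. Among 12 genes of immature neurons 4 were higher in each region, such as Stmn1 at 1.28 ± 0.12 and Gap43 at -1.09 ± 0.10. Among 12 endothelial and mural genes Cdh5 and Vtn were higher in the PFC and Cldn5 and Acta2 in the POA. Among 7 monoamine genes 3 were higher in the PFC, such as Htr2a at 0.85 ± 0.17 and Maob, and Htr2c at -1.83 ± 0.19, Htr1a and Ddc were higher in the POA. Among 7 genes of X inactivation 2610029G23Rik was higher in the PFC and Eif2s3x and Kdm5c in the POA. Among 13 cortical excitatory genes 10 were higher in the PFC (median log2 1.97) and 1, Cux1, in the POA. Maob, Ddc and Cux1 are named after their values were seen. None of the single tested genes of choroid plexus and blood differed, and no gene of the Y-linked list was tested, since the tables hold only bases with reads in every pool of a region.

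Adjusted over the list alone, the counts that differed between the regions were 12 maternal, 14 paternal, 4 isoform dependent, 2 X inactivation, 7 progenitor, 8 immature neuron, 11 oligodendrocyte, 10 astrocyte and 9 microglial genes. They were 1 endothelial, 0 choroid plexus, 0 blood, 11 cortical excitatory, 13 GABAergic, 12 preoptic, 20 synaptic, 16 immediate early and 6 monoamine genes. In all, edgeR called 6618 of 11922 genes, 3437 higher in the PFC and 3181 in the POA. Leaving out single pools ended some calls, at adjusted p up to 0.278. Acta2 and Vtn were lost without any POA pool or without the PFC F1i male or PFC F1r female pool, and Slc1a2 without any POA pool or without the PFC F1r male or PFC F1i female pool. Cdh5 was lost without the POA F1r male, either POA female, the PFC F1r male or the PFC F1i female pool. Kdm5c was lost without the POA F1r male, either POA female, the PFC F1i male or either PFC female pool. With the deepest base alone the sign turned for Begain (-0.13), Snrpn and Snurf (both -0.27), Peg13 (0.56), Kdm5c (0.62) and Htr1a (0.48).

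**Figure D4:**
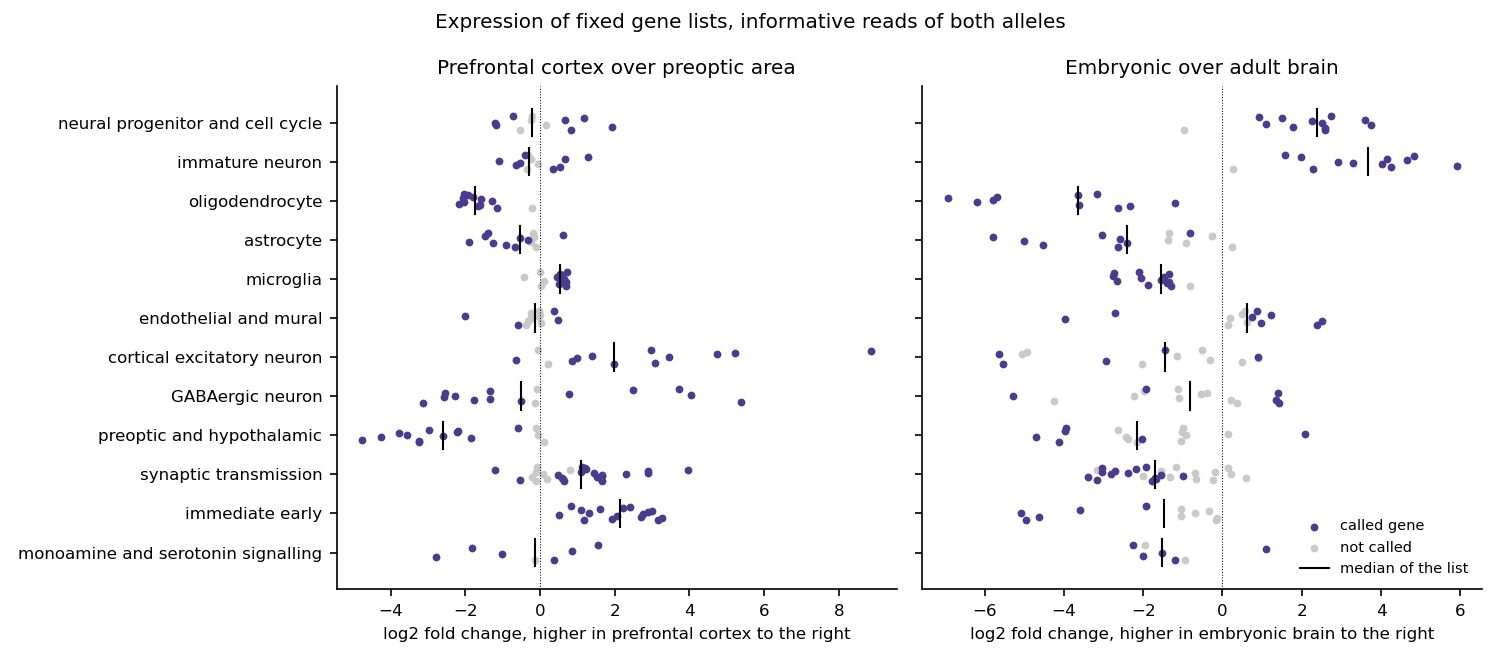
Log2 fold change of total informative reads for tested members of the gene lists between the adult regions (positive, higher in the PFC) and between embryo and adult (positive, higher in the embryo). The imprinted, X inactivation, Y-linked, choroid plexus and blood lists are not drawn. Immediate early genes lay on the PFC side and preoptic and oligodendrocyte genes on the POA side.

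Between the embryonic whole brain and the adult regions, most listed genes of progenitors and immature neurons were lower in the adult and most of oligodendrocytes, microglia, astrocytes and synapses higher. Cd24a, a surface protein of young neurons, stood at 1615 ± 239 CPM in the embryo (n = 2) and 23.7 ± 3.92 in the adult (n = 8, log2 6.09 ± 0.16). Dcx, a microtubule protein of migrating neurons, was higher in the embryo by 5.90 ± 0.21, the tubulin gene Tubb2b by 4.84 ± 0.25, Vash2 by 5.68 ± 0.39 and Igf2 by 5.12 ± 0.38. Of 12 genes of immature neurons 11 were higher in the embryo and none in the adult, as were 11 of 12 progenitor genes, such as the intermediate filament gene Vim at 2.74 ± 0.19 and Ccnd2 at 2.59 ± 0.58. All 10 oligodendrocyte genes were higher in the adult, with Mbp at 22.2 ± 7.35 in the embryo and 2700 ± 1328 in the adult and Mag at -6.19 ± 1.26. Of 13 microglial genes 12 were higher in the adult, and of 13 astrocyte genes 8, such as the lipoprotein gene Clu at -4.52 ± 0.29. Of 27 synaptic genes 14 were higher in the adult and none in the embryo, among them Snap25 at -3.03 ± 0.54. Red cell RNA was higher in the embryo, with beta globin, Hbb-b1, at 1520 ± 331 against 129.97 ± 28.1 CPM and the haem enzyme gene Alas2 at 3.34 ± 0.50, so 2 of 2 blood genes rose with the embryonic samples.

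Imprinted genes moved both ways with age. Of 20 paternally expressed genes 6 were higher in the adult, such as Rasgrf1 at -5.37 ± 0.25 and Impact at -3.27 ± 0.48, and 5 in the embryo, Igf2 and, named after their values were seen, Inpp5f, Mest, Plagl1 and Mcts2. Of 21 maternally expressed genes 5 were higher in the adult, such as Begain at -2.19 ± 0.35 and Cd81 at -1.35 ± 0.24, and 3 in the embryo, Cdkn1c, Zim1 and Rb1, named after their values were seen. Of 10 isoform or tissue dependent genes the matrix protein gene Dcn was higher in the embryo at 3.03 ± 0.23. Of 13 endothelial and mural genes 6 were higher in the embryo, such as Cdh5 at 2.38 ± 0.24, and 2 in the adult, Ly6c1 at -3.96 ± 0.37 and Slco1a4. Of 13 cortical excitatory genes Camk2a at -5.55 ± 1.46, Crym, Egr3 and Rasgrf2 were higher in the adult and Cux1 in the embryo. Of 14 GABAergic genes 3 were higher in the embryo, such as Reln at 1.39 ± 0.18 and Dlx1, and 2 in the adult, such as Pvalb. Of 15 preoptic genes 5 were higher in the adult, such as Vgf at -3.96 ± 0.34, and Slc17a6 in the embryo at 2.08 ± 0.68. Of 12 immediate early genes 5 were higher in the adult, such as Egr1 at -4.62 ± 1.49. Of 7 monoamine genes 4 were higher in the adult, such as Htr1a, Htr2a and Maob, and Maoa in the embryo. The choroid plexus gene tested, Enpp2, was higher in the adult at -1.19 ± 0.23, and 0 of 8 genes of X inactivation differed. Slco1a4, Cux1, Pvalb and Maoa are named after their values were seen.

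Adjusted over the list alone, the counts that differed with age were 8 maternal, 11 paternal, 1 isoform dependent, 0 X inactivation, 11 progenitor, 11 immature neuron, 10 oligodendrocyte, 11 astrocyte and 13 microglial genes. They were 8 endothelial, 1 choroid plexus, 2 blood, 7 cortical excitatory, 5 GABAergic, 6 preoptic, 16 synaptic, 5 immediate early and 5 monoamine genes. In edgeR 5065 of 12146 genes were called, 2672 higher in the embryo and 2393 in the adult, and age cannot be told apart from dissection here. Without the embryonic F1i pool 2751 genes were called and without the F1r pool 2807, and 38 of 68 named genes held their call without any single pool. Of the genes above, omission of either embryonic pool ended the calls of Camk2a, Egr1, Egr3, Slc17a6, Htr1a, Htr2a and Maob, and omission of the F1r pool that of Ccnd2. Maob was also lost without the POA F1i female, PFC F1i male, PFC F1r male or PFC F1r female pool. Adjusted p then rose to at most 0.272.

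Male and female adults differed little in total expression. Xist was at 13.8 ± 7.20 CPM in females and 0.457 ± 0.302 in males (n = 4 each, log2 4.79 ± 0.57, edgeR adjusted p = 0.0102), counted under 2 accessions that share the same base. Per informative reads without TMM scaling Xist lay at 3.12 CPM in the PFC F1r female pool and at 16.6 to 18.4 in the other female pools. Ddx3x and Eif2s3x were also lower in that pool, at 59.6 and 52.8 CPM, than in PFC F1i females, at 101.04 and 77.6, and PFC males had 55.7 to 60.4 and 32.5 to 42.5. The X-linked lymphocyte regulated genes Xlr3b and Xlr3c, close copies of each other, were higher in males at -1.72 ± 0.25 and -1.74 ± 0.25, both with an edgeR adjusted p of 0.0424 and both named after their values were seen. These made up the 4 calls of 11922 genes, with 619 at an unadjusted p under 0.05. Of 7 genes of X inactivation the 2 entries of Xist were called, and 5 passed when adjusted over the list alone, with Eif2s3x at 0.66, Ddx3x at 0.54 and Kdm5c at 0.41 higher in females. Of 16 immediate early genes 0 were called and 5 passed when adjusted over the list alone, Arc at 0.62, Btg2 at 0.64, Egr4 at 0.70, Fos at 0.52 and Junb at 0.52, all higher in females. Of 15 GABAergic genes 0 were called and 1 passed when adjusted over the list alone, Slc32a1 at 0.52. On each other list 0 genes were called and 0 passed when adjusted over the list alone. Members passing only over the list alone are named after their values were seen. No gene was called without the POA F1i male, POA F1r male or PFC F1i male pool, when the adjusted p of Xist rose to at most 0.242. Its log2 value stayed between 4.25 and 5.56 without any single pool. The count was 2 without any of the POA F1i female, POA F1r female and PFC F1i female pools, and 5 without the PFC F1r male or PFC F1r female pool.

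Noncoding RNAs and single genomic bases were tested in the same way. Of 11403 entries of a functional RNA database 708 were called in the embryo, 417 maternal and 291 paternal. In the POA 133 of 6023 were called, 82 maternal and 51 paternal, and in the PFC 120 of 5692, 70 maternal and 50 paternal. Entries that hold mitochondrial reads were not set apart: FR065824, with the most reads of the maternal PFC calls, stood at 98.5% in F1i and 99.9% in F1r, near mitochondrial reads. Of single genomic bases 2458 of 89658 were called in the embryo, 410 of 54279 in the POA and 269 of 47748 in the PFC. The embryonic calls held 733 bases in coding exons, 1047 in untranslated exons, 202 in noncoding exons, 274 in introns and 202 between genes. Clusters held 904 of the embryonic, 354 of the POA and 240 of the PFC calls, and the largest lay in imprinted domains. Copies of the mitochondrial genome held 59, 22 and 37 calls, some of them in clusters, and 478 embryonic calls were X-linked. In the POA 123 lay at chromosome 12:110270481-110987352, from Begain to Mirg, 103 of them maternal, and 73 at chromosome 15:72337996-72935124, which holds Trappc9, Eif2c2 and Kcnk9, 41 maternal and 32 paternal. A run of 47 paternal bases spanned Peg3 and Usp29 at chromosome 7:6656662-6919880, and 10 maternal bases lay at Asb4, a ubiquitin ligase subunit gene, at chromosome 6:5348276-5382827. In the embryo 190 called bases lay at chromosome 12:110098680-110987352, 181 maternal and 9 paternal, a stretch that also holds Dlk1. Bases of a single transcript are not independent, and the embryonic counts rest on Fisher's exact test with counting error alone.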

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

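The tests of swapped pool labels and of mitochondrial reads aligned to a nuclear copy were chosen after the result was seen. The others here were written beforehand.

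The embryonic pools gave 718 autosomal calls outside the imprinted lists, most of them near an even share. The prediction for parental expression shared with the adult brain was not met: 328 of the 617 genes tested in adults, 53.2% (95% interval 49.1 to 57.2, exact binomial p = 0.126 against 50%), had the same direction there. The interval lies above the 47.3% that the paternal lean of adult genes alone would give. By direction, 47.9% of the maternal and 64.5% of the paternal calls kept theirs, while 42.5% of all adult autosomal genes outside the lists leaned maternal. The biases were weak and genes are not independent, so this test does not decide how much of the set is shared. Spread between pools beyond counting error is a candidate explanation, since pairs of adult pools of 1 cross, which differ in sex, gave a mean of 80.8 such calls, 51.1% of the 158 between reciprocal pools and just past the bound of 50%, with 34 and 82 against 124 and 237 in the POA and 92 and 115 against 187 and 84 in the PFC. Reads counted at neighbouring SNPs cannot be told apart as a cause, because 69.4% as many genes, 498, were called with SNPs at least a read length apart, a value between the bounds set for either answer, and parental expression limited to the embryo is untested.

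X-linked reads were 97.4% maternal (Clopper-Pearson 95% interval 97.3 to 97.4) in the embryonic F1i pool and 44.5% (44.3 to 44.7) in the F1r pool. A swap of the pool labels is argued against, as mitochondrial reads, which come from the mother, were at least 98.8% maternal in both pools. A candidate explanation is fewer female embryos in the F1i pool: Xist was at 4.02 CPM there and 538.5 in F1r, 0.747% of the F1r value. This bears on any embryonic X-linked call, 78 of which were maternal. The F1i share lay within the 96.2 to 98.9% of the adult male pools. Xist coats the inactive X, so its low level in F1i argues against a parental effect as the source of the F1i share. A parental effect on the X of female embryos stays open, since each cross gave a single pool.

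Atpase6, placed on chromosome 1, was 98.2 to 99.9% maternal in every pool and made up 1.42 to 8.30% of autosomal informative reads. The prediction for parental expression of a nuclear gene was not met, with 0% of the 7 tested genes within 1 Mb called maternal in the embryo. Neighbours without a bias cannot by themselves exclude parental expression of a single gene. Mitochondrial reads aligned to a nuclear copy are a candidate explanation: chromosome 1:24618374-24623027 holds 4654 bp of the mitochondrial genome at 99.9% identity, and the maternal share differed from that of mitochondrial reads by at most 0.457 percentage points. 5830418K08Rik on chromosome 9 spans mitochondrial copies of 75.4 and 74.2% identity, where reads aligned to the genome were 45.2 and 77.8% maternal in the PFC (31 and 18 reads), unlike mitochondrial reads. The reads of its call were counted on the transcript and not placed on the genome, so the cause of that call stays open.

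The regions differed in parental bias at Begain, by 2.92 in log2 (43.0% ± 2.61 maternal in the PFC, 21.8% ± 5.04 in the POA), and at Herc3, by -2.70 (57.2% ± 4.87 and 77.3% ± 2.48), and without any single pool neither was called, at adjusted p between 0.0642 and 0.590. Of 33 splits of the 8 adult pools 11 gave as many calls as the real 2, so chance cannot be excluded for this count. The highest other split gave 335 calls, 296 of them X-linked, and the split that parted the sexes gave 297, all of them X-linked. X-linked reads differ between the sexes, so these large counts say little about chance for the 2 autosomal genes. Of autosomal calls alone 4 other splits held at least the real 2.

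Embryo and adult differed in parental bias by 14.3 in log2 for Grb10, -6.86 for Igf2, -3.92 for Inpp5f, -5.14 for Mest, 3.41 for Blcap and 3.58 for Sp140 (n = 2 and 8 pools). Mitochondrial reads, outside the comparisons of genes, made up 19.7% of informative reads in the embryonic, 11.9% in the POA and 28.0% in the PFC tables, and were 98.7 to 99.9% maternal.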

How the results depend on the processing

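The alternative with SNPs at least a read length apart, and autosomes alone for the embryo and for expression by age, were chosen after the data were seen. No paired analysis was possible because the labels link no animal or pool of 1 group to a member of another. Of the named genes' values under all alternatives, 3624 kept their direction and their side of the threshold, 303 kept the direction but no longer passed, and 7 reversed. All 7 reversals came with the deepest SNP of each gene: Nap1l4 in strain bias (-0.39) and, between regions in expression, Begain (-0.13), Peg13 (0.56), Snrpn and Snurf (both -0.27), Kdm5c (0.62) and Htr1a (0.48). The cause was not tested. The deepest SNP also gave 477 embryonic calls, 2148 strain calls and 0 region differences of bias, and 43.3% for the X-linked maternal share of the embryonic F1r pool. It gave r = 0.661 and rho = 0.557 between parents and F1 alleles, and it uses fewer reads per gene by construction. DESeq2 called 81 genes in the POA, 91 in all adult pools and 17 region differences, and the cause was not tested. Tests with counting error alone called 610 genes in the POA, 461 in the PFC, 590 in all adult pools, 163 for sex, 287 for region and 893 for age differences of bias. The same kind of test gave 328 and 289 functional RNAs and 1650 and 1193 genomic bases in the POA and PFC. These tests leave out the spread between pools by construction. The embryo with the adult spread gave 104 calls. Dropping the rule on sides admitted genes with shares on different sides of 50% by construction and gave 2000 embryonic genes, 1328 functional RNAs and 4691 genomic bases. A share of at least 70% left 75 embryonic calls (31 maternal and 44 paternal) and about 1.1e+02 strain calls (70 higher from CAST and 44 from B6). Autosomes alone gave 133 calls in the POA, 49 in the PFC and 78 in all adult pools. Of 86 POA calls gained in this way 7 were on the imprinted lists, and 72 were paternal, at a median maternal share of 41.2%. The direction was that of the embryo for 43 of the 82 tested there. For calls gained in the PFC it was so for 13 of 17, and in all adult pools for 21 of 33. The cause of the gains was not tested. SNPs a read length apart gave 1 sex difference of bias, and expression by sex without covariates 0 calls. The X-linked maternal share was 99.5% in adult males as a median over genes. In the embryonic F1i pool it was 97.5% over genes of at least 50 reads and 98.4% as a median, and in F1r 44.7% without SNPs of a low allele and 43.5% as a median. For parents and F1 alleles r was 0.693 and rho 0.582 with at least 50 reads, and 0.668 and 0.557 with a pseudocount of 5. The cause of these shifts was not tested.

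Leaving out each pool in turn gave 20 to 51 calls in the POA, 10 to 29 in the PFC, 41 to 47 in all adult pools and 3273 to 3591 for strain. It gave 0 to 29 differences of bias by sex, 0 to 0 by region and 3 to 7 by age, and 5616 to 6749 expression calls by region, 2751 to 5067 by age and 0 to 5 by sex. The highest sex count, 29, came without the PFC F1r female pool. The lowest POA counts came without the F1i male pool (21) or the F1i female pool (20), the lowest PFC count of 10 without either F1i pool, and the lowest age expression counts without an embryonic pool (2751 and 2807). Age differences of bias without an embryonic pool could not be estimated, since a cross then has no embryonic pool. Omission of technical replicates and a block for them were not run because the authors summed them. With 4 pools, simulated shares of 60% were recovered for 0% of genes in the POA and 3% in the PFC, and with 8 adult pools for 46.5%.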

Other observations

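The 2 tests of chromosome 7 below were chosen after the result was seen, and the splits of the pools were planned. The genes of this and the next paragraph were chosen after their values were seen. In the POA the maternal list reached Calcr, the calcitonin receptor gene, at a mean of 98.1% maternal (n = 4, log2 11.69 ± 0.56, edgeR adjusted p = 0.00259), Asb4 at 94.3% ± 1.25 and the zinc finger gene Zim1 at 88.1% ± 6.93. All 3 were also maternal in the embryo (n = 2), Calcr at 96.4% ± 1.68, Asb4 at 91.7% ± 4.54 and Zim1 at 83.3% ± 6.01. Cdkn1c, a brake on the cell cycle, was 95.9% ± 0.696 and Igf2r, the receptor that clears IGF2, 65.3% ± 5.55 maternal in the embryo. Magel2 (nS7), of the Prader-Willi region, was 1.71% ± 2.41 maternal in the embryo and 6.19% ± 5.53 in the POA.

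Xlr3a, Xlr3b and Xlr3c, X-linked close copies, were called maternal in all adult pools at 81.6% ± 14.6, 82.3% ± 14.3 and 82.1% ± 16.1 (n = 8, edgeR adjusted p = 0.00509, 0.0019 and 0.0121). In the F1r females, whose X-linked reads as a whole were 34.7% ± 4.34 maternal, they were 87.2% ± 10.2, 89.2% ± 8.25 and 90.9% ± 12.9 maternal (n = 2 each). In the F1i females the means lay between 73.9% ± 8.03 and 77.4% ± 6.56. Male F1i pools, whose X is maternal, stood at 64.3% ± 11.9, 67.2% ± 12.2 and 65.4% ± 14.3, so some of their reads carried the B6 base at these copies. Such reads would count as maternal in F1r, where the mother was B6. The F1r female values therefore do not by themselves show a parental bias. Xlr3b had 316 and Xlr3c 267 informative reads over the 8 pools.

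Genes at 100 to 110 Mb of chromosome 7 leaned to the father in the POA, with a median maternal share of 44.5% over 40 genes outside the imprinted lists. This was the lowest of 160 windows, -7.92 SD from the others, and the second lowest without the F1i male or the F1r female pool. On the same chromosome 30 to 40 Mb stood at 44.7% over 48 genes and 90 to 100 Mb at 46.9% over 15. Single pools stood at 37.3% in F1r females, 45.1% in F1r males, 46.8% in F1i males and 47.8% in F1i females. Against the other windows of the same pool these lay at -7.44, -3.86, -1.73 and -1.33 SD. A segment in 1 pool that is not heterozygous is argued against as the whole cause, since the window still lay at -5.50 SD without the F1r female pool, though the share then moved to 46.5%. A bias shared with the PFC cannot be told apart from none, since the window lay at -1.45 SD there and at -4.64 SD without the PFC F1r male pool and 0.725 SD without the PFC F1r female pool. In the embryo it lay at -0.526 SD. A segment common to both F1r pools may contribute to the value of -5.50 SD and was not tested.

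Other splits of the 8 adult pools were counted for each test across genes. For parental calls in all adult pools, 2 of 35 splits gave as many as the real 48, so this count alone does not exclude chance. The other such split parted the regions, so its 288 calls are differences of allele share between the POA and the PFC and not between arbitrary groups. The remaining 33 splits gave 0. For sex differences of bias all 33 splits that could be fitted gave at least the real 0, the highest other 86. For expression between regions 1 of 33 splits, the real one with 6618 calls, was as large and the highest other gave 0. This met the bound set beforehand against chance. The other splits leave the region difference in the spread between pools, which lowers their counts, so the 0 there is weak evidence. For expression between sexes 1 of 33 was as large as the real 4 and the highest other gave 2, which met the same bound for the count of 4 as listed. The bound was not met with Xist, under 2 accessions, and the close copies Xlr3b and Xlr3c each taken once. The 2 calls of the other split are separate genes, and 2 of 33 splits are then as large.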
